A study of Mus musculus with 18 samples.

How the data were processed

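The study holds 18 mouse liver libraries, 6 from control WT, 6 from tumour-bearing WT and 6 from tumour-bearing Alb-Cre+/+;Stat3f/f mice. Per the labels, livers were kept in TRIzol, RNA was isolated with RNeasy Mini columns and libraries were made with the Quantseq 3′ FWD kit of Lexogen, which sequences from the 3′ end of polyadenylated RNA. The authors aligned reads with STAR to mm10. The version of STAR, the counting tool, the annotation, the read filters and the strand setting are not given in the sources used here, so reads of overlapping or antisense transcripts cannot be separated. The deposited table holds counts, raw and not normalized, with 1 column per library and 24421 gene symbols. Its 18 columns were matched to the samples by the numbers in the labels, with 0 columns left over.

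Of the 24421 symbols 27 had been turned into spreadsheet date numbers and were left out (0.103 to 0.166% of the counts), which leaves 24394. Positions came from RefSeq on GRCm38.p6, the assembly of mm10, for 24274 of them (99.5%). The total count per library ran from 5212265 to 9545442, and edgeR gave a common biological coefficient of variation of 0.281. Thinned to the smallest library, the first comparison called again 90.1%, the second 89.9% and the third 87.7% of their genes.

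Tests were run in R 4.3.3 with edgeR 4.0.16. TMM factors were computed, filterByExpr kept 11218 genes, and a quasi-likelihood fit (glmQLFit, 1 coefficient per group, all 18 libraries, 15 residual degrees of freedom) was tested for each of 3 contrasts. All tests are two-sided, and adjusted p are Benjamini-Hochberg values over the 11218 genes, with a threshold of 0.05. SE are standard errors of the log2 fold change. CPM use TMM-scaled library sizes. The number of livers in a direction counts livers of the first-named group whose log2 CPM lies on that side of the mean of the second-named group; for a list it uses the mean over its members.

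There were 35 gene lists (22 of functions and 13 of cell type or handling markers), of which 30 had at least 5 measured members. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, against an estimated correlation and against fry, which asks whether a list's genes move one way and compares them with no other genes. List p-values are adjusted over the 30 lists. The groups, contrasts, lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are Stat3, Saa1, Saa2, Saa3 and Socs3, then per contrast genes from the 8 largest increases and 8 largest decreases among called genes with a mean of at least 10 CPM (predicted genes, pseudogenes and Mup genes left out), and from each list described up to 4 members with the smallest adjusted p. From these, the text names mainly genes whose call no single left-out library ends.

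Alternatives were DESeq2 1.42.0, RLE size factors, library totals without TMM, no and a stricter filter (1 CPM in 6 libraries), the 2 groups of a contrast alone, limma voom with quality weights, the replicate number or the label-number run as a block, and leaving out each library in turn. The fit with the label-number run as a block held the 2 WT groups only. Thinning, fits within each label-number run, leaving out libraries for the list counts, the count away from Stat3, other splits of the 2 groups alone, and splits of the control libraries were added after seeing the data. DESeq2 gave no adjusted p for 9 genes per contrast. The numbers of shared genes were compared with the 20 splits of the shared group into 3 and 3, and the covariance of the fold changes with 20 simulations of unchanged groups. The procedure was tested on simulated data: of 100 genes changed 2-fold it recovered 60 in the first, 58 in the second and 60 in the third contrast, of 100 changed 4-fold 93, 93 and 96, and it called 4, 5 and 7 unchanged genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 read the table, and matplotlib 3.10.9 drew the plots. Shares of a single library carry 95% Wilson intervals, which cover counting error only.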

Results

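RNA was measured by 3′ tag sequencing, which reads the end of each polyadenylated transcript, in 18 mouse livers that fall into 3 groups of 6. The groups are control wild-type (WT) livers, livers of tumour-bearing WT mice, and livers of tumour-bearing Alb-Cre+/+;Stat3f/f mice, called Stat3-deleted here. Alb-Cre drives Cre recombinase in hepatocytes, where it removes the floxed part of Stat3, the transcription factor that relays IL-6 family cytokines. The tumour line, PDA.69, is a mouse pancreatic ductal adenocarcinoma line. The labels list this line for the control livers too and give no site or time of implantation, sex or age. No group holds tumour-free Stat3-deleted livers. The total count per library was 5212265 to 7159148 in control, 6168658 to 8850200 in tumour-bearing WT and 7222882 to 9545442 in Stat3-deleted livers, and 13386 to 14094 genes had at least 1 count. The series title names serum amyloid A, whose genes Saa1 and Saa2 together took 0.037% ± 0.0236 of the counts in control (SD, n = 6), 2.84% ± 2.53 in tumour-bearing WT and 0.0074% ± 0.0125 in Stat3-deleted livers. The 20 most abundant genes took 24.4 to 26.1% of the counts in control, 24.5 to 35.1% in tumour-bearing WT and 26.4 to 29.7% in Stat3-deleted livers.

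The first comparison, tumour-bearing WT against control WT livers, asks what changes in the liver of a tumour-bearing mouse. Acute-phase genes held 6 of the 8 largest increases among called genes with a mean of at least 10 CPM. Saa1 (mm10 chromosome 7, 46740497 to 46743181), which encodes a plasma apolipoprotein of the acute phase, rose from 246 ± 168 to 18290 ± 15943 CPM (counts scaled to a common library total; SD, n = 6), a log2 fold change of 6.21 (SE 0.73, adjusted p = 1.84e-05). Its neighbour Saa2 (46751833 to 46754313) rose from 103 ± 70.5 to 13546 ± 13394 CPM, by 7.04 on the log2 scale (SE 1.11, adjusted p = 0.000542). The pair are near-identical in sequence, and their summed count rose by 6.51 (SE 0.86, adjusted p = 7.71e-05). Saa3 (46711998 to 46719615) rose less, from 31.5 ± 12.6 to 103 ± 66.1 CPM, a log2 fold change of 1.72 (SE 0.33, adjusted p = 0.0054). Each of the 3 genes was higher in 6 of 6 livers.

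Of the 32 measured positive acute-phase genes, 26 rose and 6 did not pass the test. Adjusted over the list alone, 28 rose and 1 fell. The list's median log2 fold change was 1.71, it was higher in 6 of 6 livers, and camera gave an adjusted p of 6.49e-46, with adjusted p = 0.00788 with an estimated correlation. Besides the Saa genes, Fgl1, a hepatocyte-secreted fibrinogen-like protein, rose from 383 ± 87.7 to 3444 ± 1472 CPM, a log2 fold change of 3.17 (SE 0.25, adjusted p = 6.93e-08). Lcn2 (chromosome 2, 32384637 to 32387739), which encodes a siderophore-binding protein, rose from 6.77 ± 3.53 to 414 ± 287 CPM (log2 fold change 5.94, SE 0.54, adjusted p = 4.73e-07). Orm2 (chromosome 4, 63362449 to 63365877), an orosomucoid gene, rose from 5.04 ± 1.51 to 359 ± 289 CPM (6.16 on the log2 scale, SE 0.53, adjusted p = 2.07e-07). Apcs (chromosome 1, 172893961 to 172895054), which encodes serum amyloid P, rose from 122 ± 53.8 to 2144 ± 1727 CPM (4.14, SE 0.47, adjusted p = 1.57e-05). The metallothionein gene Mt2 (chromosome 8, 94172618 to 94173567) rose by 4.27 (SE 0.82, adjusted p = 0.00469). All of these were higher in 6 of 6 livers. Of 18 measured genes of negative acute-phase and secreted plasma proteins, 1 rose and 0 fell (5 and 0 adjusted over the list alone). Their median was 0.25, or 0.007 with library totals alone, and 4 of 6 livers were higher. Camera gave an adjusted p of 0.0338, and of 0.54 with an estimated correlation.

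**Figure D1:**
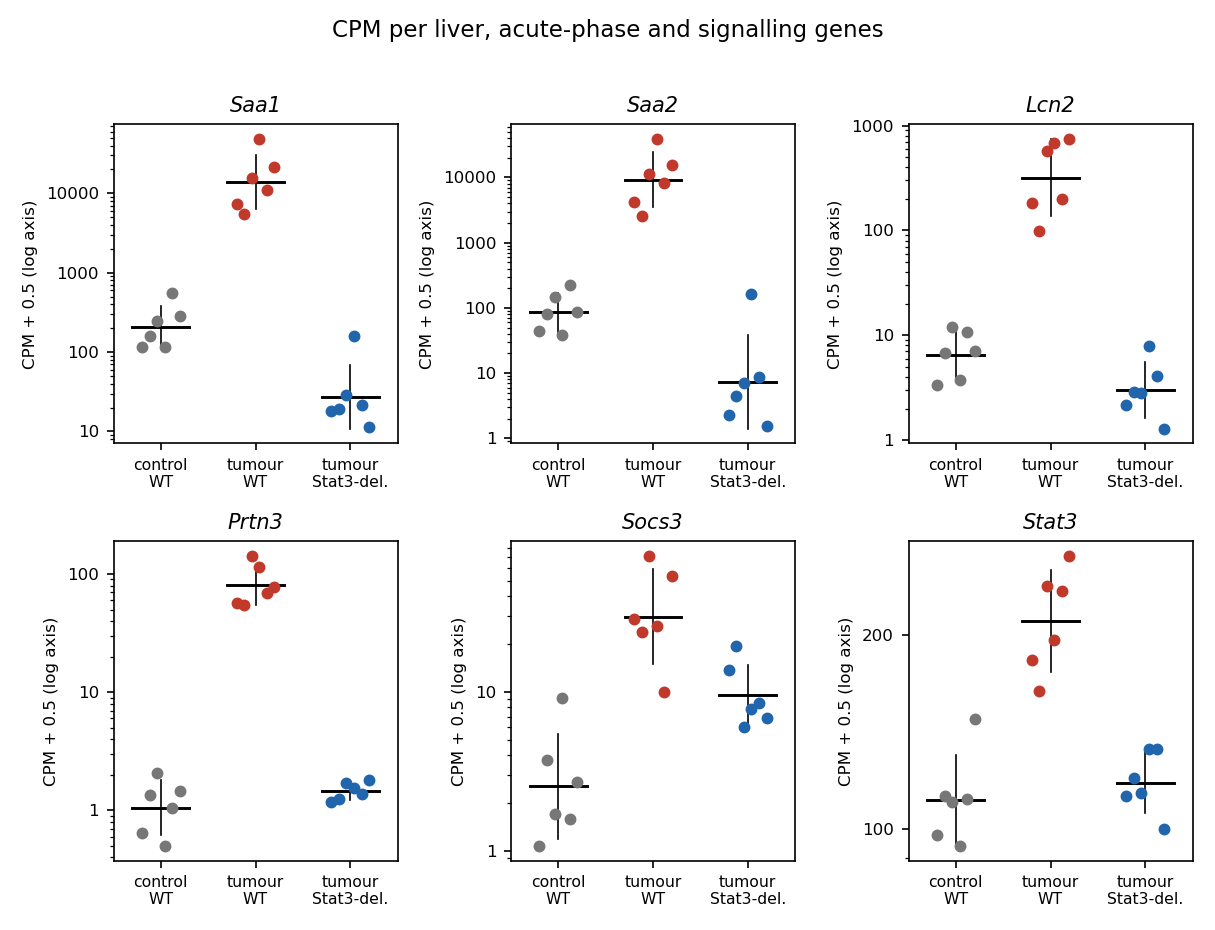
Expression of 6 genes in each of the 18 livers, as CPM + 0.5 on a log axis, with 1 point per liver in the control WT, tumour-bearing WT and tumour-bearing Stat3-deleted groups of 6; the horizontal line is the mean and the vertical line 1 SD, both on the log scale. Saa1, Saa2, Lcn2 and Prtn3 were higher in every tumour-bearing WT liver than in any liver of the other groups.

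Prtn3 (chromosome 10, 79879667 to 79883174), which encodes the neutrophil serine protease proteinase 3, had one of the smallest adjusted p of this comparison. It rose from 0.678 ± 0.574 to 85.4 ± 35.1 CPM, a log2 fold change of 6.99 (SE 0.39, adjusted p = 6.9e-11), in 6 of 6 livers. Of 9 measured neutrophil markers, 4 rose (6 adjusted over the list alone), with a list median of 1.56 (camera adjusted p = 2.67e-06; adjusted p = 0.0474 with an estimated correlation). S100a9, a calcium-binding protein abundant in neutrophils, rose from 13.7 ± 5.57 to 79.3 ± 44.3 CPM (2.54, SE 0.35, adjusted p = 0.000141), and its partner S100a8 rose by 2.67 (SE 0.38, adjusted p = 0.000197). Of 12 chemokines and inflammatory cytokines, 4 rose (adjusted over the list alone, 6 rose and 1 fell), with a median of 0.95 (camera adjusted p = 1.12e-06; adjusted p = 0.0745 with an estimated correlation). Cxcl1 (chromosome 5, 90891245 to 90893121), a neutrophil-attracting chemokine, rose from 5.16 ± 1.20 to 85.3 ± 53.9 CPM (4.04, SE 0.42, adjusted p = 2.88e-06). Cxcl14 (chromosome 13, 56288643 to 56296811) rose by 4.09 (SE 0.57, adjusted p = 0.000141) and Ccl6 by 1.67 (SE 0.34, adjusted p = 0.00774). These genes and both lists were higher in 6 of 6 livers.

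Markers of resident and recruited macrophages were higher as lists in 6 of 6 livers. Of 13 Kupffer cell markers 2 rose (7 adjusted over the list alone; median 0.57, camera adjusted p = 1.74e-05; adjusted p = 0.257 with an estimated correlation). Of 18 monocyte and macrophage markers 3 rose (8 adjusted over the list alone; median 0.92, camera adjusted p = 5.61e-07; adjusted p = 0.244 with an estimated correlation). Vsig4, a complement receptor of Kupffer cells, rose by 0.95 (SE 0.22, adjusted p = 0.0237) in 6 of 6 livers. Its call was lost without control replicate 1 (adjusted p = 0.0572), 4 (0.0592) or 6 (0.058), or without tumour-bearing WT replicate 3 (0.0676) or 4 (0.0813). The 9 T and NK cell markers had a median of −0.10 (camera adjusted p = 0.974).

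Stat3 itself and genes of IL-6 signalling were higher in tumour-bearing WT livers. Stat3 (chromosome 11, 100886806 to 100939594) rose from 112 ± 19.1 to 213 ± 38.3 CPM, a log2 fold change of 0.93 (SE 0.14, adjusted p = 0.000302), and Socs3 (chromosome 11, 117966079 to 117970336), a feedback inhibitor of IL-6 signalling, from 2.84 ± 3.01 to 35.0 ± 22.5 CPM (3.60, SE 0.52, adjusted p = 0.000205). Of 24 measured genes of IL-6 and STAT3 signalling, 6 rose and 1 fell (adjusted over the list alone, 12 and 2). The list median was 0.53, or 0.33 with library totals alone (camera adjusted p = 1.57e-05; adjusted p = 0.0183 with an estimated correlation). Junb rose by 1.76 (SE 0.23, adjusted p = 5.37e-05) and Il6st, the shared receptor chain of the IL-6 family, by 0.69 (SE 0.14, adjusted p = 0.0061). Of 30 complement and coagulation genes, 7 rose (11 adjusted over the list alone), with a median of 0.24, or 0.03 with library totals alone (camera adjusted p = 3.77e-05; adjusted p = 0.201 with an estimated correlation). They include Hc, which encodes complement C5 (chromosome 2, 34983329 to 35068506; 0.80, SE 0.12, adjusted p = 0.000257), and C4b (1.23, SE 0.18, adjusted p = 0.000257). The genes named here and the 2 lists were higher in 6 of 6 livers.

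Several lists of hepatocyte functions were lower in tumour-bearing WT livers with the preset correlation, and each of these calls was lost with an estimated correlation. Of 29 cytochrome P450 and drug metabolism genes 2 fell (6 adjusted over the list alone), with a median of −0.32, in 5 of 6 livers (camera adjusted p = 0.00018; adjusted p = 0.257 with an estimated correlation). Fatty acid oxidation and ketogenesis had a median of −0.24 over 29 genes, or −0.41 with library totals alone, in 6 of 6 livers (camera adjusted p = 0.000485; adjusted p = 0.257 with an estimated correlation); 0 of its genes passed in edgeR, 5 had an unadjusted p under 0.05, and 2 passed in DESeq2 and 1 in limma voom. Cholesterol synthesis was higher, with a median of 0.43 over 23 genes, or 0.23 with library totals alone, in 4 of 6 livers, with 1 gene higher and 8 adjusted over the list alone (camera adjusted p = 0.000452; adjusted p = 0.422 with an estimated correlation). Of 15 male-biased hepatocyte genes 3 fell (4 adjusted over the list alone), with a median of −0.98 in 5 of 6 livers (camera adjusted p = 6.09e-05; adjusted p = 0.355 with an estimated correlation). The 5 measured female-biased genes had a median of −0.96 too, with 1 fallen (camera adjusted p = 0.855). Of 4 measured Y-linked genes 0 passed in edgeR, DESeq2 or limma voom and 0 had an unadjusted p under 0.05, and Y-linked Ddx3y was at 116 to 208 CPM in all 18 livers. Among single genes, Gsta2, a glutathione transferase (chromosome 9, 78331018 to 78347192), fell from 42.3 ± 34.7 to 8.67 ± 5.54 CPM (−2.29, SE 0.47, adjusted p = 0.00788). Etnppl, an ethanolamine phosphate lyase (chromosome 3, 130617448 to 130635750), fell from 142 ± 43.4 to 43.5 ± 30.3 CPM (−1.71, SE 0.34, adjusted p = 0.0061). Both were lower in 6 of 6 livers. Cyp2a4, a steroid-hydroxylating P450 gene, had the largest negative log2 fold change among genes of at least 10 CPM, −5.17 (SE 1.34, adjusted p = 0.0417, lower in 5 of 6 livers). That call rested on control replicate 2, without which its adjusted p was 0.816. It was also lost without tumour-bearing WT replicate 2 (0.0666), 3 (0.11), 4 (0.111), 5 (0.0664) or 6 (0.0798), or without Stat3-deleted replicate 1 (0.0553), 2 (0.0531) or 3 (0.0537).

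In all, 252 of 11218 tested genes differed between tumour-bearing and control WT livers at an adjusted p under 0.05 in edgeR, 197 higher and 55 lower, and 150 of them by at least 2-fold. Of 30 tested lists camera called 17, 11 higher and 6 lower, and 3 of the calls held with an estimated correlation: positive acute-phase proteins, IL-6 and STAT3 signalling, and neutrophil markers. Fry called 7 lists. The gene count was 444 without tumour-bearing WT replicate 1, 133 without replicate 3 and 139 without replicate 4 of that group, and 162 without control replicate 4 and 160 without control replicate 6. The lower genes numbered 182 without tumour-bearing WT replicate 1 and 17 without replicate 3. DESeq2 called 462 genes and a fit of the 2 groups alone 128. Identifying numbers in the labels put replicates 1 to 3 of both WT groups in a lower run and 4 to 6 in a higher one. With the run as a block, in a fit of the 2 groups alone, the count was 126, against 128 without the block. It was 38 and 51 within the lower and higher run, 3 livers against 3. Within these runs the log2 fold change of Saa1 was 5.76 (adjusted p = 5.48e-05) and 6.40 (adjusted p = 0.00664). Scaling by library totals alone shifted the median of all genes by −0.19, and the higher share of the called genes from 78.2% to 39.4%, so the balance of directions in the full set depends on the scaling.

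**Figure D2:**
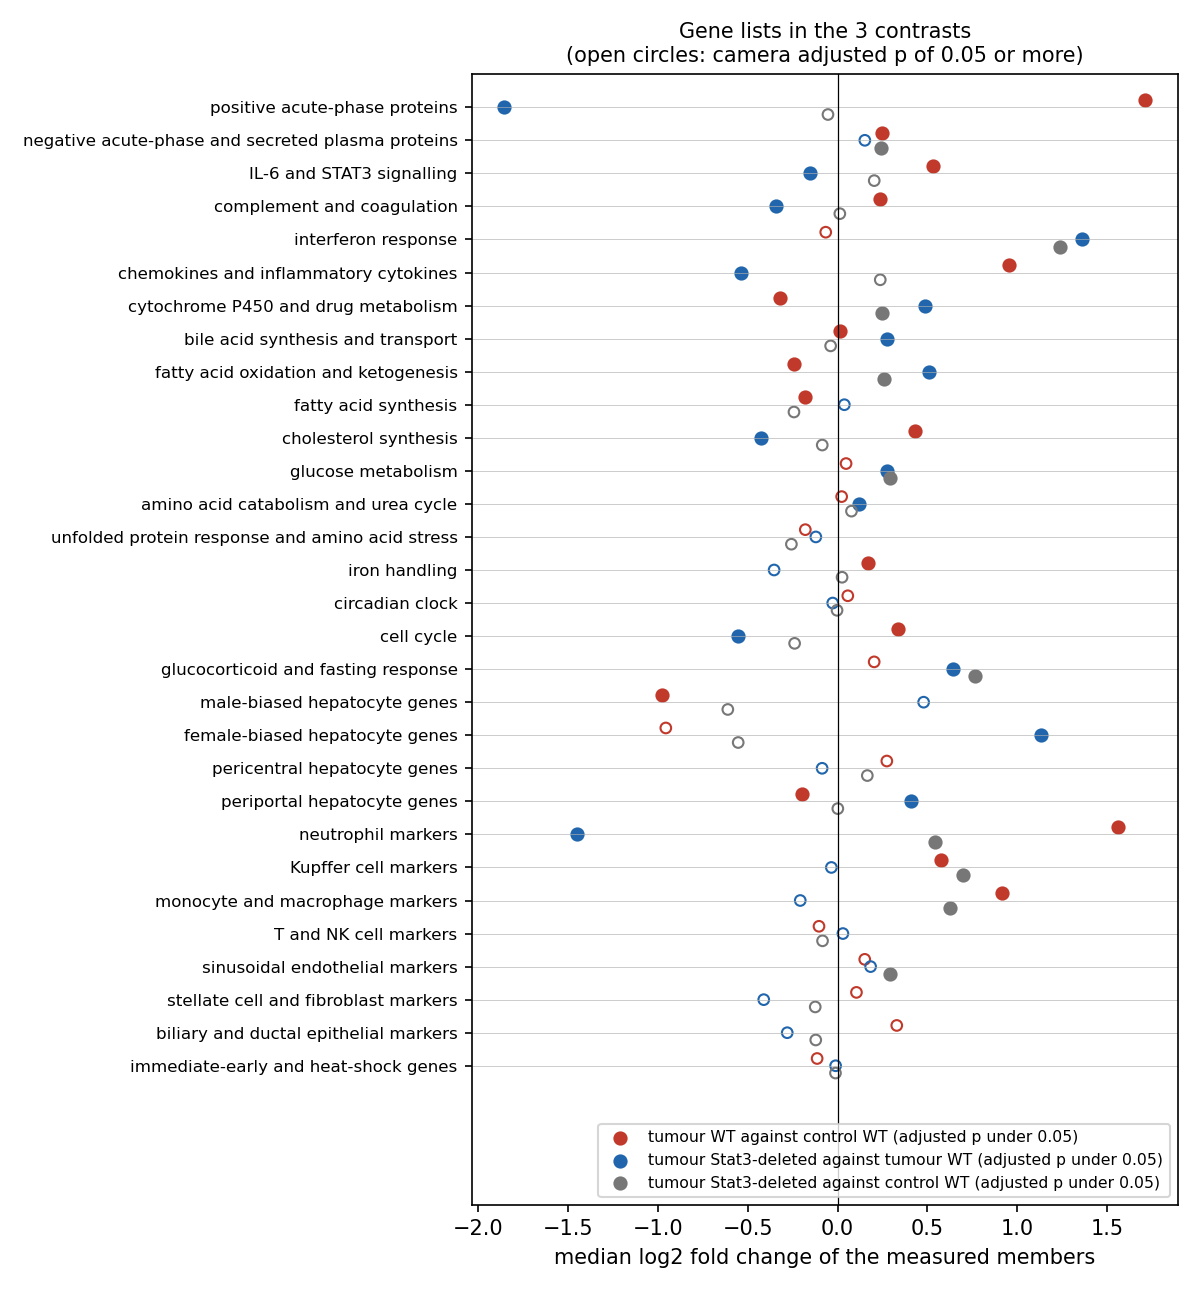
Median log2 fold change of the measured members of each of the 30 tested gene lists in the 3 comparisons, 1 point per list and comparison; filled points have a camera adjusted p under 0.05 with the preset correlation, open points 0.05 or more. Positive acute-phase proteins lie at 1.71 for tumour-bearing against control WT and −1.86 for Stat3-deleted against tumour-bearing WT, and interferon response genes at −0.07 and 1.36.

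The second comparison, tumour-bearing Stat3-deleted against tumour-bearing WT livers, asks how the liver of a tumour-bearing mouse differs when its hepatocytes lack Stat3. The acute-phase genes were lower. Saa1 fell from 18290 ± 15943 to 42.9 ± 58.0 CPM, by −8.73 on the log2 scale (SE 0.82, adjusted p = 3.08e-07), Saa2 from 13546 ± 13394 to 31.2 ± 66.0 CPM, by −8.76 (SE 1.20, adjusted p = 5.3e-05), and their sum by −8.75 (SE 0.95, adjusted p = 2.84e-06). Without Stat3-deleted replicate 4 the log2 fold change of Saa1 was −9.88 (adjusted p = 1.11e-08) and that of Saa2 −11.59 (adjusted p = 6.24e-08). Saa3 fell to 23.0 ± 10.6 CPM (−2.16, SE 0.34, adjusted p = 0.000257). Lcn2 fell to 3.01 ± 2.32 CPM (−7.08, SE 0.58, adjusted p = 4.15e-08), Orm2 to 3.60 ± 1.68 (−6.63, SE 0.55, adjusted p = 4.15e-08) and Apcs to 95.6 ± 10.0 (−4.49, SE 0.48, adjusted p = 2.31e-06). Fgl1 had a log2 fold change of −4.37 (SE 0.27, adjusted p = 3.03e-10). Of the 32 positive acute-phase genes, 23 fell and 2 rose (27 and 2 adjusted over the list alone), with a median of −1.86 (camera adjusted p = 3.23e-32; adjusted p = 0.0376 with an estimated correlation). All the genes named here and the list were lower in 6 of 6 livers.

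Stat3 fell from 213 ± 38.3 to 118 ± 12.8 CPM, a log2 fold change of −0.85 (SE 0.14, adjusted p = 0.00043), in 6 of 6 livers. The tag lies at the 3′ end of the transcript, so its level does not measure whether the floxed exons were removed. Socs3 fell from 35.0 ± 22.5 to 9.88 ± 5.14 CPM (−1.83, SE 0.46, adjusted p = 0.0182) in 6 of 6 livers. This call was lost without tumour-bearing WT replicate 3 (adjusted p = 0.0702) or Stat3-deleted replicate 3 (0.0507). Socs3 lies within 20 Mb of Stat3, where strain variants linked to the floxed allele and an effect of Stat3 loss cannot be told apart. Of the 24 genes of IL-6 and STAT3 signalling 6 fell (adjusted over the list alone, 8 fell and 3 rose), with a median of −0.15, or −0.08 with library totals alone, in 6 of 6 livers (camera adjusted p = 0.0409; adjusted p = 0.251 with an estimated correlation). Its call was lost without tumour-bearing WT replicate 3 (0.0614) or 6 (0.128), or Stat3-deleted replicate 1 (0.0501) or 6 (0.0574). Tifa, an adaptor protein, fell by −1.80 (SE 0.25, adjusted p = 5.98e-05). Of 30 complement and coagulation genes 8 fell (9 adjusted over the list alone), with a median of −0.34 in 6 of 6 livers (camera adjusted p = 4.88e-05; adjusted p = 0.178 with an estimated correlation). Hc fell from 978 ± 118 to 356 ± 25.4 CPM (−1.46, SE 0.12, adjusted p = 4.15e-08). Tifa and Hc were lower in 6 of 6 livers.

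Prtn3 fell to 0.974 ± 0.246 CPM, a log2 fold change of −6.43 (SE 0.36, adjusted p = 1.04e-10), and Cxcl1 to 1.84 ± 1.28 CPM (−5.51, SE 0.46, adjusted p = 4.24e-08). Scara5, a ferritin receptor (chromosome 14, 65666403 to 65764826), fell from 37.5 ± 18.3 to 0.978 ± 0.639 CPM (−5.26, SE 0.78, adjusted p = 0.00013). Of 12 chemokines and inflammatory cytokines 4 fell and 1 rose (5 and 1 adjusted over the list alone; median −0.54, camera adjusted p = 0.00285; adjusted p = 0.279 with an estimated correlation). The one that rose was Ccl9 (1.09, SE 0.17, adjusted p = 0.000221). Of 9 neutrophil markers 4 fell (4 adjusted over the list alone), with S100a9 at −1.70 (SE 0.34, adjusted p = 0.003) and S100a8 at −1.64 (SE 0.37, adjusted p = 0.00764). The neutrophil list had a median of −1.45 (camera adjusted p = 0.0476; adjusted p = 0.385 with an estimated correlation). Its call was lost without control replicate 1 (0.0567) or 6 (0.0503), tumour-bearing WT replicate 3 (0.11), 4 (0.092) or 6 (0.0654), or Stat3-deleted replicate 1 (0.0501), 2 (0.0718), 4 (0.0775) or 6 (0.0558). The genes that fell and both lists were lower in 6 of 6 livers, and Ccl9 was higher in 6 of 6.

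Interferon-inducible genes were higher in Stat3-deleted livers. Igtp (chromosome 11, 58199556 to 58207592), an interferon-inducible GTPase, rose from 29.0 ± 5.74 to 480 ± 292 CPM, a log2 fold change of 4.05 (SE 0.50, adjusted p = 1.72e-05). Iigp1 (chromosome 18, 60373616 to 60392634), of the same family, rose from 588 ± 182 to 3296 ± 1671 CPM (2.49, SE 0.34, adjusted p = 4.51e-05), and Irgm2 (chromosome 11, 58214977 to 58222783) from 11.1 ± 5.44 to 50.3 ± 18.4 CPM (2.18, SE 0.32, adjusted p = 0.00014). Each rose in 6 of 6 livers. Gbp7, a guanylate-binding protein (chromosome 3, 142530336 to 142550151), rose from 39.9 ± 11.4 to 197 ± 122 CPM (2.30, SE 0.38, adjusted p = 0.000489) in 5 of 6 livers. Of 30 measured interferon response genes 20 rose (23 adjusted over the list alone), with a median of 1.36 in 6 of 6 livers (camera adjusted p = 3.01e-17; adjusted p = 0.155 with an estimated correlation). Against control WT livers the same list had a median of −0.07, or −0.25 with library totals alone, in tumour-bearing WT livers (3 of 6 lower; camera adjusted p = 0.855), where edgeR, DESeq2 and limma voom called 0 of its genes and 1 had an unadjusted p under 0.05. The spread between Stat3-deleted livers was wide, with Igtp at 71.5 CPM in replicate 6 and 854 CPM in replicate 5. The 9 T and NK cell markers had a median of 0.03 (camera adjusted p = 0.498), and the 13 Kupffer cell markers one of −0.03, or 0.04 with library totals alone (camera adjusted p = 0.916).

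**Figure D3:**
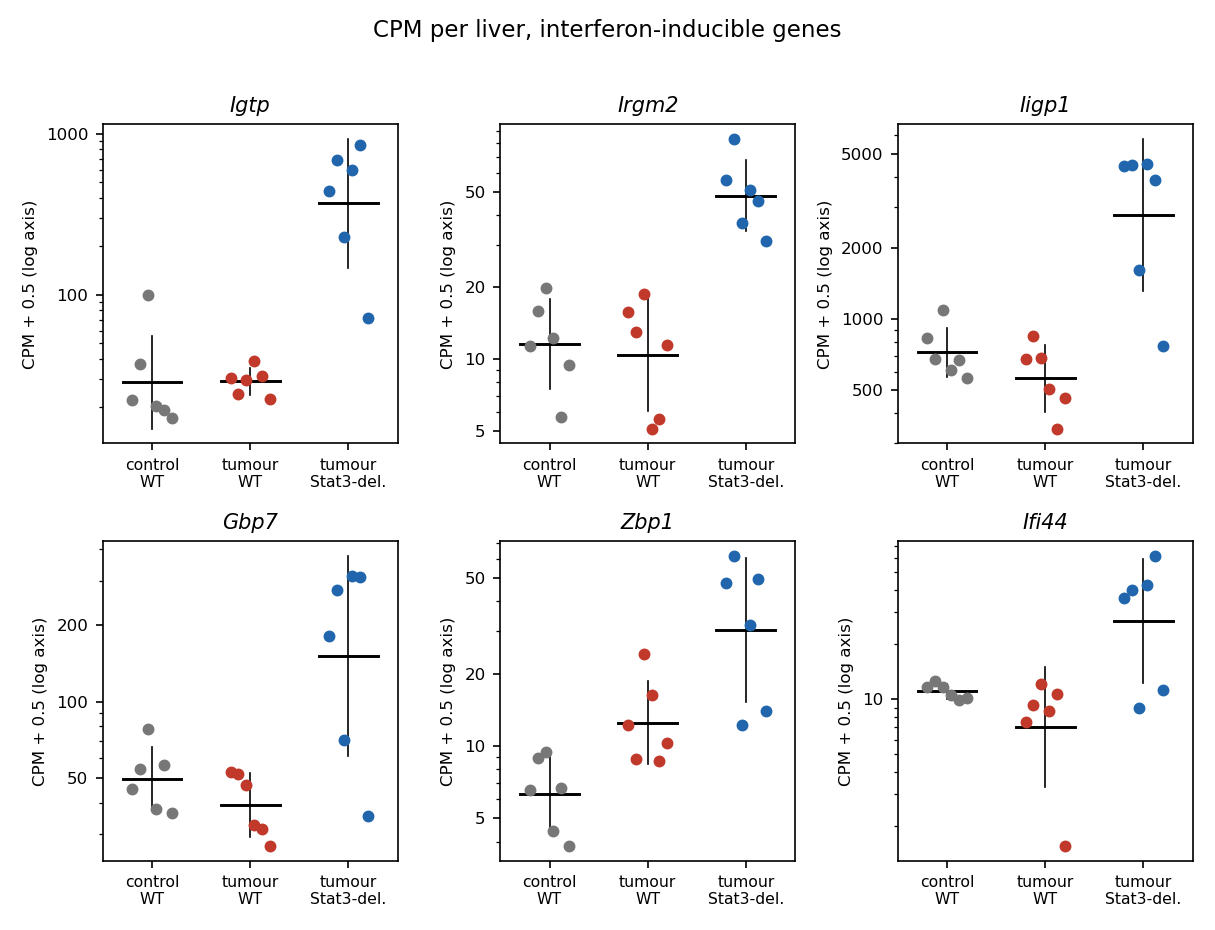
Expression of 6 interferon-inducible genes in each of the 18 livers, as CPM + 0.5 on a log axis, with 1 point per liver in the control WT, tumour-bearing WT and tumour-bearing Stat3-deleted groups of 6; the horizontal line is the mean and the vertical line 1 SD, both on the log scale. Means for Igtp were 35.5, 29.0 and 480 CPM, and the Stat3-deleted livers spread from 71.5 to 854 CPM.

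Several metabolic lists also differed between the tumour-bearing groups with the preset correlation, and none of those calls held with an estimated correlation. With fry, which compares a list with no other genes, the lists named here had adjusted p from 0.00118 to 0.0414. Of 29 cytochrome P450 and drug metabolism genes 9 rose (adjusted over the list alone, 12 rose and 1 fell), with a median of 0.48 (camera adjusted p = 6.66e-10; adjusted p = 0.0735 with an estimated correlation). Gstm1, a glutathione transferase, rose from 1076 ± 376 to 2863 ± 611 CPM (1.41, SE 0.24, adjusted p = 0.000661), and Nr1i2, which encodes the pregnane X receptor, by 0.81 (SE 0.16, adjusted p = 0.00324). Of 29 genes of fatty acid oxidation and ketogenesis 9 rose (18 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 6.66e-10; adjusted p = 0.0735 with an estimated correlation). The examples are Acot1, an acyl-CoA thioesterase (2.00, SE 0.34, adjusted p = 0.000604), and Cpt2, a carnitine palmitoyltransferase (0.51, SE 0.12, adjusted p = 0.0131). Cholesterol synthesis was lower, with 6 of 23 genes fallen (10 adjusted over the list alone) and a median of −0.43 (camera adjusted p = 2.18e-05; adjusted p = 0.309 with an estimated correlation). Sqle, squalene epoxidase, fell by −0.98 (SE 0.23, adjusted p = 0.0107). Of 18 glucocorticoid and fasting genes 5 rose (6 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 2.04e-06; adjusted p = 0.292 with an estimated correlation), among them Zbtb16 (1.79, SE 0.32, adjusted p = 0.00109). Of 22 glucose metabolism genes 5 rose and 3 fell (8 and 3 adjusted over the list alone; median 0.27, camera adjusted p = 0.00699; adjusted p = 0.155 with an estimated correlation). Foxo1, a transcription factor of gluconeogenic genes, rose by 0.94 (SE 0.20, adjusted p = 0.0045) and Ldha, lactate dehydrogenase A, fell by −0.86 (SE 0.17, adjusted p = 0.00277). Gsta2 rose by 2.57 (SE 0.47, adjusted p = 0.00146). These lists and genes kept their direction in 6 of 6 livers.

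Between the 2 tumour-bearing groups 686 of 11218 genes differed in edgeR, 324 higher and 362 lower in Stat3-deleted livers, and 306 by at least 2-fold. Of 30 lists camera called 16, 9 higher and 7 lower, and with an estimated correlation 1 call held, that of positive acute-phase proteins. Fry called 14 lists. In limma voom with quality weights the gene count was 1097, the higher genes numbered 212 without tumour-bearing WT replicate 3 and 210 without 4, and scaling by library totals alone moved the higher share from 47.2% to 61.1%. This contrast also holds any effect of the genotype without a tumour, and the Stat3-deleted livers carry label numbers in a run of their own, so run and genotype cannot be told apart.

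The third comparison, tumour-bearing Stat3-deleted against control WT livers, differs in tumour and genotype together and is read beside the others. Saa1 fell below its control level, from 246 ± 168 to 42.9 ± 58.0 CPM (−2.52, SE 0.62, adjusted p = 0.0235), in 6 of 6 livers. That call was lost without control replicate 5 (adjusted p = 0.0573) or Stat3-deleted replicate 2 (0.058), 3 (0.0608) or 5 (0.0604), and without Stat3-deleted replicate 4 the log2 fold change was −3.68 (adjusted p = 0.000941). Saa2 had a log2 fold change of −1.71 (SE 0.89, adjusted p = 0.278), or −4.57 (adjusted p = 0.00118) without Stat3-deleted replicate 4, and the sum of both genes −2.23 (SE 0.71, adjusted p = 0.0713). Stat3 had one of 0.08 (SE 0.14, adjusted p = 0.803) and Saa3 one of −0.45 (SE 0.33, adjusted p = 0.471). Socs3 was higher than in control livers by 1.77 (SE 0.52, adjusted p = 0.049) in 6 of 6 livers, but leaving out any of 13 libraries gave adjusted p from 0.0513 (without tumour-bearing WT replicate 4) to 0.137 (without Stat3-deleted replicate 2). The 13 are control replicates 1 (0.107), 2 (0.0646), 3 (0.0997), 5 (0.11) and 6 (0.0974), tumour-bearing WT replicates 1 (0.0583), 2 (0.0572) and 4, and Stat3-deleted replicates 1 (0.094), 2, 3 (0.0621), 5 (0.0748) and 6 (0.0538). Of the 32 positive acute-phase genes 2 rose and 3 fell (5 and 3 adjusted over the list alone), with a median of −0.05, or −0.18 with library totals alone, in 3 of 6 livers (camera adjusted p = 0.754). Fgl1 fell to 167 ± 32.0 CPM (−1.20, SE 0.24, adjusted p = 0.00712) and the IL-1 receptor antagonist gene Il1rn rose by 1.87 (SE 0.37, adjusted p = 0.00712), each in 6 of 6 livers.

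Of the 30 interferon response genes 18 were higher than in control livers (24 adjusted over the list alone), with a median of 1.23 in 6 of 6 livers (camera adjusted p = 3.83e-16; adjusted p = 0.34 with an estimated correlation). Igtp was higher by 3.77 (SE 0.49, adjusted p = 0.000354), Iigp1 by 2.15 (SE 0.33, adjusted p = 0.000857), and Zbp1, an interferon-inducible nucleic acid sensor (chromosome 2, 173206612 to 173218959), by 2.54 (SE 0.38, adjusted p = 0.000682). Of 18 glucocorticoid and fasting genes 3 rose (10 adjusted over the list alone; median 0.76, camera adjusted p = 1.92e-06; adjusted p = 0.34 with an estimated correlation), with Lpin1, a phosphatidate phosphatase (chromosome 12, 16535669 to 16653903), at 2.02 (SE 0.45, adjusted p = 0.013). Kupffer cell markers had a median of 0.70 (3 of 13 rose and 1 fell; 8 and 1 adjusted over the list alone; camera adjusted p = 0.000101; adjusted p = 0.34 with an estimated correlation), and the neutrophil list one of 0.54 (camera adjusted p = 0.0135; adjusted p = 0.34 with an estimated correlation), in which 1 of 9 genes rose, Hdc (1.01, SE 0.23, adjusted p = 0.0164; 4 adjusted over the list alone). Lower genes include C9, of the membrane attack complex (−1.45, SE 0.21, adjusted p = 0.000573), Cib3 (chromosome 8, 72204335 to 72213086; −2.67, SE 0.41, adjusted p = 0.000857) and Irs2, an insulin receptor substrate (chromosome 8, 10984681 to 11008929; −2.19, SE 0.44, adjusted p = 0.00763). Every gene and list named here kept its direction in 6 of 6 livers.

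Against control WT livers 544 of 11218 genes differed in edgeR, 246 higher and 298 lower, and 224 by at least 2-fold; camera called 10 of 30 lists, all higher, of which 0 held with an estimated correlation and fry called 1. The gene count was 259 without Stat3-deleted replicate 5, 273 without 2 and 278 without 3 of that group, and 343, 306 and 362 without control replicates 1, 4 and 5. DESeq2 called 860 genes, a fit of the 2 groups alone 894 and limma voom 1318, and with library totals alone the median of all genes was −0.13, against −0.01 with TMM, and the higher share moved from 45.2% to 27.2%. Without Stat3-deleted replicate 4, 238 genes were higher and 532 lower.

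The first 2 comparisons were set side by side to ask which tumour-associated changes ran the other way in Stat3-deleted against tumour-bearing WT livers. A gene that does so may still differ from control livers, as Socs3 did in the main fit. Of the 197 genes higher in tumour-bearing WT than in control livers, 109 (55.3%) were lower in Stat3-deleted than in tumour-bearing WT livers. With fits of the 2 groups alone the count was 68 in place of 109. The genes with the largest changes in both were Saa2, Saa1, Prtn3, Lcn2 and Orm2. Independent calls would give 6.36 shared genes. Both contrasts share the tumour-bearing WT libraries, which alone makes them opposed. Over all genes their correlation was −0.525, against −0.501 in simulated unchanged groups, and their covariance −0.136 against −0.0429. The simulations gave every group the same spread per gene. A wider spread among tumour-bearing WT livers would alone make the covariance more negative, so its excess does not show a shared effect. With the tumour-bearing WT livers split 3 and 3, so that no library served both contrasts, the 20 splits gave 38 to 72 shared genes with a median of 55. Independent calls within those splits would give at most 9.05. Of the 55 genes lower in tumour-bearing WT livers, 22 (40%) were higher in Stat3-deleted livers, against 1.59 from independent calls. The splits gave 0 to 13 such genes with a median of 1, where independent calls within the splits would give at most 6.00. Within single splits the counts went both ways, such as 13 against 3.81, 10 against 6.00 and 1 against 2.68 from independent calls. The second count was 8 with fits of the 2 groups alone, 57 with DESeq2, 65 with library totals alone and 38 with limma voom. It was 8 without tumour-bearing WT replicate 3, 11 without 4, 51 without 1 and 60 without 5.

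**Figure D4:**
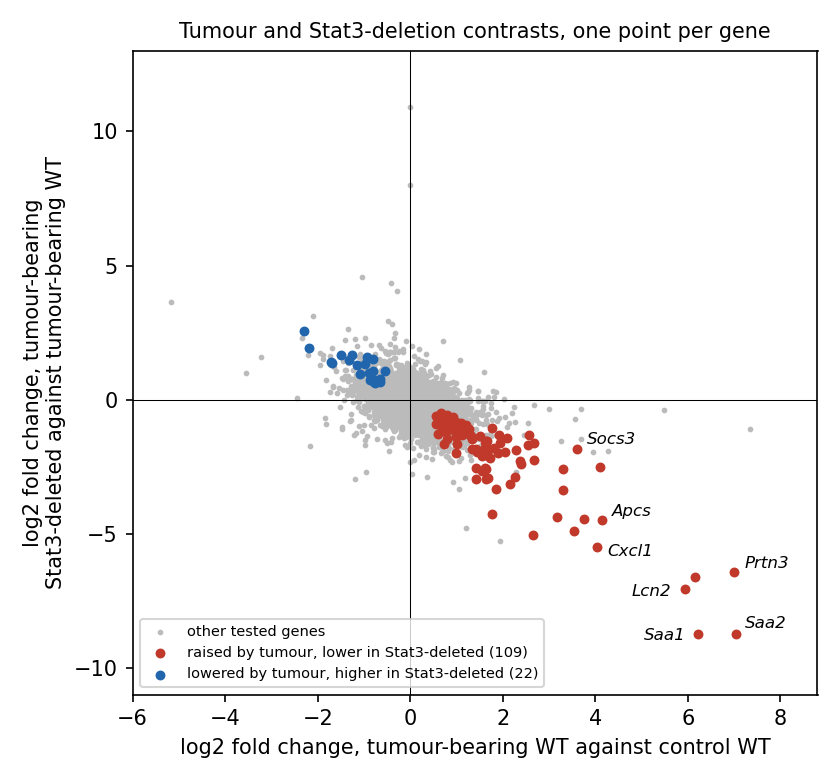
Log2 fold change of each of the 11218 tested genes between tumour-bearing and control WT livers (x axis) and between Stat3-deleted and tumour-bearing WT livers (y axis), 1 point per gene. Coloured points are the 109 genes higher in the first and lower in the second comparison and the 22 genes that did the reverse; the lower right holds Saa1, Saa2, Prtn3, Lcn2, Cxcl1, Apcs and Socs3.

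Fewer genes differed from control livers in the same direction in both tumour-bearing groups. Of the 197 raised genes, 28 were also higher in Stat3-deleted than in control livers, against 4.32 from independent calls, 12 were lower and 157 passed neither way; their median log2 fold change was 1.27 in tumour-bearing WT and 0.23 in Stat3-deleted livers. Both contrasts share the control libraries, which raises this overlap. With the control livers split 3 and 3, so that no control library served both contrasts, the 20 splits gave 2 to 8 such genes with a median of 3. Independent calls within those splits would give a median of 0.385 and at most 1.75. Over all genes the 2 contrasts had a correlation of 0.395, below the 0.505 of the simulations, and a covariance of 0.0946 against 0.0435. As the simulations gave every group the same spread per gene, neither difference shows or excludes a shared effect. Timp1, a metalloproteinase inhibitor, was higher than in control livers by 3.56 in tumour-bearing WT (SE 0.54, adjusted p = 0.000314) and 2.83 in Stat3-deleted livers (SE 0.54, adjusted p = 0.00604). Inhbb, which encodes the beta B subunit of activin, was higher by 2.68 (SE 0.51, adjusted p = 0.0043) and 2.47 (SE 0.51, adjusted p = 0.00864), and Mgp, matrix Gla protein, by 1.74 (SE 0.30, adjusted p = 0.00181) and 1.44 (SE 0.30, adjusted p = 0.00965). Between the 2 tumour-bearing groups their log2 fold changes were −0.73 (adjusted p = 0.37), −0.20 (adjusted p = 0.848) and −0.30 (adjusted p = 0.609). These 3 genes were chosen after their values were seen, and each was higher than in control livers in 6 of 6 livers of both groups. Of the 55 lowered genes 14 were also lower in Stat3-deleted than in control livers, against 1.46 from independent calls. Of the rest, 1 was higher and 40 passed neither way. The splits of the control livers gave 0 to 3 genes lower in both groups, with a median of 1. Within those splits independent calls would give a median of 0.108 and at most 0.791. The urinary protein gene Mup20 was lower than in control livers by −1.83 in tumour-bearing WT (SE 0.44, adjusted p = 0.0244) and by −2.54 in Stat3-deleted livers (SE 0.45, adjusted p = 0.00318), in 6 of 6 livers of each. The first call was lost without control replicate 4 (adjusted p = 0.0581), 5 (0.0533) or 6 (0.056), or tumour-bearing WT replicate 3 (0.0597) or 6 (0.0514).

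The labels do not state that each library comes from a separate animal, so the p-values measure the spread between these livers, part of which may be technical.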

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

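None of the tests in this part was chosen after its result was seen. In each group of 6 livers, the gap between the highest or lowest liver and its nearest neighbour was divided by the group's range, for 37 named genes on the scale of log2(CPM + 2) and for 5 measures of the libraries. Of 126 such groups 14 had a ratio above the critical value of Dixon's test for 6 values. For independent values chance would give about 6.3, or 1 in 20. Most of the genes were picked for large fold changes in these livers, and Saa1, Saa2 and their share overlap. The excess is therefore not read as a test.

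Saa1 and Saa2 stood apart in Stat3-deleted replicate 4. Saa1 was at 161 CPM there and at 10.7 to 28.3 CPM in the other 5 livers (ratio 0.659), and Saa2 at 166 against 1.03 to 8.35 CPM (ratio 0.694). The share of both genes in that library was 0.0328% (95% Wilson interval 0.0317 to 0.0341%), against 0.001 to 0.003% in the others (ratio 0.931). Tumour-bearing WT replicate 4 had a share of 7.78% (95% Wilson interval 7.77 to 7.80%), against 0.87 to 2.81% in the others (ratio 0.72). Saa3 was at 57.0 CPM in control replicate 3 and at 24.8 to 29.2 CPM in the other controls (ratio 0.807).

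Control replicate 2 was high in Cyp2a4, at 138 CPM against 0.137 to 2.59 CPM (ratio 0.817), and in Fkbp5, at 35.0 against 7.81 to 13 CPM (ratio 0.68). In tumour-bearing WT replicate 6, Fkbp5 was at 221 against 13 to 29.6 CPM (ratio 0.724), Wdfy1 at 16.8 against 1.71 to 4.74 CPM (ratio 0.631), and Ifi44 was the lowest at 1.06 against 6.96 to 11.6 CPM (ratio 0.722). That library also had the lowest TMM factor, 0.75. Cyp2a4 was at 2.94 CPM in tumour-bearing WT replicate 1 against 0 to 0.395 CPM (ratio 0.801), and Meiob at 20.4 CPM in control replicate 3 against 11.1 to 12.7 CPM (ratio 0.786). Among Stat3-deleted livers, Gsta2 was at 107 CPM in replicate 6 against 33.1 to 50.5 CPM (ratio 0.644), and Lpin1 at 474 CPM in replicate 2 against 342 to 385 CPM (ratio 0.637).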

How the results depend on the processing

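Thinning, fits within label-number runs, leaving out libraries for the list counts, and the count away from Stat3 were chosen after the results were seen. Of the named-gene values under the alternatives other than leaving out 1 library at a time, 536 kept their side of the threshold. Another 41 kept their direction but missed the threshold, and 2 passed it. Of values called in the main fit or the alternative, 0 turned direction, while direction was not counted for values called in neither. Of the 41, 21 come from fits of 3 livers against 3. For tumour-bearing against control WT the gene count of 252 became 462 with DESeq2 and 128 with the 2 groups alone. Adding the label-number run as a block to the fit of the 2 groups alone gave 126. The count was 38 and 51 within the lower and higher run, and 133 to 444 when each library was left out in turn. For Stat3-deleted against tumour-bearing WT 686 became 1097 with voom and 465 to 896 with a library left out; without the 36 placed within 20 Mb of Stat3, 650 are left, of which 1 has no known position. For Stat3-deleted against control WT 544 became 860 with DESeq2, 894 with the 2 groups alone, 1318 with voom and 259 to 780 with a library left out. The 109 raised genes that were lower in Stat3-deleted livers became 68 with the 2 groups alone and 74 to 130 with a library left out, and the 22 lowered genes that were higher became 57 with DESeq2, 65 with library totals, 8 with the 2 groups alone, 38 with voom and 8 to 60 with a library left out. Called lists numbered 17, 16 and 10; an estimated correlation gave 3, 1 and 0, fry 7, 14 and 1, and a left-out library 13 to 18, 11 to 20 and 9 to 14. For these changes the cause was not tested. With the replicate number as a block the gene counts were 219, 710 and 570, the shared genes 96 and 23, and the lists 17, 13 and 10; livers of the same number did not go together, since 4 of 18 correlations between them were above 0.1 (−0.126 to 0.309), so these numbers are not read as pairs. No called gene turned direction when 1 library was left out; 120 of 252, 390 of 686 and 204 of 544 calls were kept in all 18 cases. Saa2 against control WT passed the threshold in Stat3-deleted livers with the block (−3.74, adjusted p = 0.0115), with voom (−3.92, adjusted p = 0.00273) and without Stat3-deleted replicate 4 (−4.57, adjusted p = 0.00118). At this depth and spread, 2-fold changes were recovered in 58 to 60 of 100 simulated genes, so a gene not called may still differ by 2-fold.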

Other observations

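Of the tests in this part, those of the genes near and away from Stat3, thinning and the splits with the 2 groups alone were chosen after results were seen. Some cell type markers moved between the tumour-bearing groups without their list being called. Jchain, the joining chain of plasma cell antibodies (chromosome 5, 88519809 to 88527897), had means of 16.5 CPM in control, 21.1 in tumour-bearing WT and 2.89 in Stat3-deleted livers, a log2 fold change of −2.87 between the tumour-bearing groups (SE 0.53, adjusted p = 0.00158). Only 4 B and plasma cell markers were measured, and their list was not tested. Of 11 biliary and ductal markers, which ductal tumour cells also express, 1 rose and 1 fell in tumour-bearing WT against control livers (4 and 2 adjusted over the list alone). Sox9 (chromosome 11, 112782210 to 112787757) was the marker that rose (1.31, SE 0.24, adjusted p = 0.00276). It fell in Stat3-deleted against tumour-bearing WT livers (−1.35, SE 0.24, adjusted p = 0.000883). Sox9 lies within 20 Mb of Stat3, where linked variants and Stat3 loss cannot be told apart. Spp1, osteopontin, fell in the second contrast (−2.06, SE 0.38, adjusted p = 0.00139), and the list had camera adjusted p of 0.304 and 0.106. Rgs5, a pericyte gene, fell by −1.14 (SE 0.26, adjusted p = 0.00894) among 20 stellate cell and fibroblast markers (camera adjusted p = 0.191). The changes of the named genes held in 6 of 6 livers.

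Single genes of iron uptake, the clock and the unfolded protein response passed the test. Tfr2, transferrin receptor 2, rose with the tumour by 0.71 (SE 0.14, adjusted p = 0.0061) and fell in Stat3-deleted livers by −0.68 (SE 0.14, adjusted p = 0.00386), and the zinc and iron transporter gene Slc39a14 by 1.00 (SE 0.22, adjusted p = 0.013) and −1.32 (SE 0.22, adjusted p = 0.000476). The iron list of 15 genes had a median of 0.17 in the first contrast, or −0.04 with library totals alone (camera adjusted p = 0.00633, or 0.244 with an estimated correlation). In the second contrast 1 of its genes rose and 3 fell (2 and 3 adjusted over the list alone), with a median of −0.35 (camera adjusted p = 0.0709). Of 17 clock genes 3 rose in Stat3-deleted against tumour-bearing WT livers, among them Nr1d1 (1.14, SE 0.24, adjusted p = 0.00509; camera adjusted p = 0.181). Herpud1, of the unfolded protein response, rose by 1.12 (SE 0.22, adjusted p = 0.00266; camera adjusted p = 0.916 over 24 genes). Each named gene moved in 6 of 6 livers.

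Chance groupings of the livers gave fewer called genes than the real groups. Of 100 splits of the 12 livers of each contrast, the real one included and the third group kept in the fit, 1 gave as many genes, the real one, in each of the 3 contrasts. The highest other split gave 133 genes against 252 for tumour-bearing against control WT, 90 against 686 for Stat3-deleted against tumour-bearing WT, and 250 against 544 for Stat3-deleted against control WT, which argues against chance as the source of each count. With the 12 livers of a contrast fitted alone, the real groups gave 128, 609 and 894 genes and the highest other split 31, 148 and 524.

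The 686 genes called between the tumour-bearing groups could come from strain variants carried along with the floxed Stat3 allele, or from library depth. Outside 20 Mb of Stat3 lie 94.7% of the calls with a known position. There 6.02% of the placed genes were called, against 8.53% within 20 Mb. The calls outside cannot come from variants that act only on genes in that window. The window holds 422 tested genes, fewer than the 686 calls, so calls outside it were certain whatever the cause. The share outside is therefore not a test of such variants. Nor can this share decide on a linked variant that acts on genes elsewhere, since that would spread the calls over the genome. After thinning every library to the smallest total 89.9% were called again, which argues against library depth as the source of the whole set. Of 422 tested genes within 20 Mb, 36 were called against tumour-bearing WT (odds ratio 1.45, 95% interval 0.995 to 2.07, Fisher's exact p = 0.0385), 32 against control WT (1.64, 1.10 to 2.39, exact p = 0.011), and 12 between the WT groups (1.29, 0.652 to 2.32, exact p = 0.399). For the genes near Stat3, linked variants and an effect of Stat3 loss cannot be told apart, since genotype and locus go together in this design. The label-number run stays open for the whole set. Between the 2 runs of the WT livers, each with 3 control and 3 tumour-bearing livers, 1 gene was called. That fit held no term for the tumour, so the tumour effect widened its spread and run differences may be missed. The run of the Stat3-deleted livers holds no WT liver to compare.

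The rise of interferon response genes in Stat3-deleted livers could reflect more T and NK cells. It could also reflect variants on chromosome 11, where Stat3, Igtp and Irgm2 lie, that act only on genes of that chromosome. Without its 4 members on chromosome 11 the list had a median of 1.09 over 26 genes, 16 of them higher (unadjusted camera p = 4.7e-15; unadjusted p = 0.0289 with an estimated correlation, where the full list had an unadjusted p of 0.0259 and an adjusted p of 0.155, a lost call), which argues against those variants as the source of the whole rise. Variants on chromosome 11 that act on genes elsewhere stay open, since they could raise the other 26 genes too. The T and NK cell markers had a median of 0.03 with an upper 95% bootstrap limit of 0.669, under the 1.36 of the interferon list. The bootstrap resampled the 9 markers and not the livers, so this limit does not cover the spread between livers. In edgeR 0 of the markers had an unadjusted p under 0.05, and as a list they were higher in 4 of 6 livers. For these livers the values argue against a gain of those cells as large as the rise of the list. A smaller gain stays open, since the limit lies above 0, and whether it could raise the list was not tested. Loss of Stat3 in hepatocytes, an effect of genotype that precedes the tumour, infection or housing, and the label-number run all stay open, as the series has no tumour-free Stat3-deleted livers.

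The rise of Prtn3 in tumour-bearing WT livers could reflect neutrophil precursors, which carry it with Elane, Mpo and Ctsg. In control and tumour-bearing WT livers, Elane was at 0.260 and 1.46 CPM, Mpo at 0.235 and 1.21 CPM and Ctsg at 0.0523 and 0.122 CPM. Their summed rise was 2.65% of the rise of Prtn3, which argues against such cells as the source of the whole rise. Which cells transcribe Prtn3 stays open, since bulk RNA cannot name them.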
